A study of Mus musculus with 3 samples.

How the data were processed

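Total RNA from melan-a NRAS61K cells, a line of immortalized mouse melanocytes carrying the NRAS61K oncogene, was measured on Affymetrix arrays after 6, 14 or 28 days with doxycycline at 1 µg/ml. Per the labels, RNA was extracted with a column kit and biotin-labelled cRNA was prepared by the array maker's standard protocol. Each time point had 1 array. The series text counts 4 samples, of which 3 were analysed here, and no untreated array was used here.

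The deposited table held 1 value per probe set and array for 45101 probe sets, 64 of them controls. The values were on a log2 scale as far as the values themselves show, since the deposited labels name neither the log base nor the method of summarization, which is not given in the sources used here. The 3 columns held the same values once sorted, so they had been quantile normalized by the authors before deposit. A difference common to most genes is removed by that step and cannot be seen in the genes. Every difference below is thus relative to the other genes. Control probe sets for added poly-A RNA had means of 23.96, 24.19 and 24.41 in order of time. Their rise was larger than that of the hybridization controls described below (27.68, 27.76 and 27.80). Whether equal amounts of poly-A RNA were added is not known here, so a common fall of the genes was neither derived nor excluded. The values ran from 1.46 to 30.6 with a median of 22.9 on each array, so a constant had been added or another scaling applied, which the labels do not state. Differences between arrays were read as if a constant had been added, since it cancels there, and this was not tested. The base of 2 was inferred. Hybridization controls of known concentration gave slopes of 0.78 to 0.80 per log2 unit of concentration, and the span from the median silent gene to the 99.9th percentile was 9.13 to 9.20. Every fold below assumes this base, and the slopes below 1 show that folds of these controls were smaller on the arrays than in concentration.

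Probe sets were named through the platform annotation, with symbols updated by gene identifier through a gene table of assembly GRCm38.p6, which was used only for names and for the order of genes along chromosomes. A single gene was given for 34958 probe sets and several for 932, while 9211 were not listed and stay unnamed here. For each of 18194 genes the probe set with the highest mean over the 3 arrays was used. The background of each array was the 90th percentile of 90 probe sets of 66 genes fixed as silent in pigment cells, such as those of liver, pancreas, muscle and sperm. It was 22.62 at day 6, 22.63 at day 14 and 22.83 at day 28. A gene entered a comparison when it lay above the background on at least 1 of the 2 arrays. For a named gene whose dimmer array lay at or below the background, the difference was given as a lower bound against the background. Gene counts, list medians and time patterns used the values as measured, also below the background.

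With 1 array per time point there is no estimate of the spread between cultures. No p-value, SD or interval between cultures is given for any difference between arrays. The bootstrap ranges in the closing part were drawn over genes, so they describe the genes on these arrays, and the number of arrays limits the precision. Genes were counted as 2-fold apart at a log2 difference of 1 or more. The only measure of error at hand was the disagreement between probe sets of one gene, which covers measurement and not culture. The SD of the log2 differences between probe sets of a gene was 0.32 for day 28 against day 6, 0.31 for day 14 against day 6 and 0.24 for day 28 against day 14. The median log2 difference of each of 25 gene lists was set beside 10000 random lists of the same size, matched on mean level in 20 bins. A list was said to stand apart where its percentile lay outside the central 95%, which describes the arrays and not the time points. Lists with fewer than 5 members above the background were not ranked. Of 677 list entries, 626 were matched to a gene on the array.

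The lists, the comparisons, the alternatives and the rule for named genes were fixed before the data were examined. For day 28 against day 6 the rule took the 12 highest and 12 lowest differences among genes above the background on both arrays, and for each other comparison the 6 highest and 6 lowest. It added per comparison and direction up to 4 genes above the background on 1 array only, up to 4 members of each list with the largest differences, the reference genes, and Nras, Cdkn2a, Cdkn1a and Cth. Other genes are named only where the text says so. The alternatives covered the scaling, the choice of probe set, the background, the treatment of dim values and the size of difference. A shift to equal hybridization controls was added after the data were examined.

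Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The steps were tested on simulated data with 18194 genes, for each of the 3 comparisons. The simulated noise was normal, with the robust SD of the disagreement between probe sets (0.24, 0.22 and 0.17). Changes were planted only in genes well above the background. All of 200 planted genes were recovered (100% at log2 sizes of 1.5 and of 3), and 0% of unchanged genes were called. Of 100 lists with no shift, 9 stood apart for day 28 against day 6, 5 for day 14 against day 6 and 6 for day 28 against day 14, and all 100 lists shifted by 0.5 did so. Differences between the real arrays were wider, with SDs of 0.60, 0.59 and 0.37. The simulation therefore checks the calculation and gives no error rates for the real data.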

Results

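Expression was followed in doxycycline-treated melan-a NRAS61K cells at 3 time points, 6, 14 and 28 days, with 1 array each. The title of the series concerns tumorigenic cells derived from cells made senescent by this oncogene, so the time course addresses how expression differs as treatment continues. No replicate arrays were analysed here, and a difference below describes 2 arrays. Of 18194 genes, 11499 lay above the background at day 6, 11442 at day 14 and 11228 at day 28, and 12015 did so on at least 1 array. The background was highest at day 28 (22.83 against 22.62 and 22.63), so the lower count there need not mean fewer expressed genes. The 3' minus 5' log2 difference of the RNA quality probe sets was 0.58, 0.76 and 0.75 for Actb and -0.24, -0.10 and -0.09 for Gapdh, in order of time. Across the 10770 genes above the background on all arrays, which are not independent replicates, Pearson's r was 0.930 between days 6 and 28, 0.934 between days 6 and 14 and 0.974 between days 14 and 28.

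Day 28 against day 6 asks how far the cells had moved from the earliest array. Genes of DNA replication and of mitosis were lower at day 28, while the medians of the pigment cell, glial and antigen processing lists were higher. The helicase subunit gene Mcm5 was 3.61-fold lower, Tk1, which makes thymidine monophosphate, 3.54-fold lower, and the mitotic kinase gene Plk1 3.49-fold lower. The milk protein gene Csn3 was 40.8-fold higher and the pigment enzyme gene Dct 18.4-fold higher. Igf2, a growth factor gene, lay below the background at day 6 and was at least 57.2-fold higher at day 28. In all, 765 genes were at least 2-fold higher and 481 at least 2-fold lower among 11837 described. With each array shifted to equal hybridization controls, a scaling added after the data were examined that moved the median of all genes by -0.12, 624 were higher and 652 lower. Such a shift moves every gene alike and turns the balance by itself, so it is no evidence about single genes.

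Of 29 DNA replication genes, 21 were 2-fold lower and 0 higher, and the median log2 difference was -1.23 against a random range of -0.19 to 0.24. Of 29 mitosis genes, 21 were again lower and 0 higher, with a median of -1.23, and Birc5 was 3.27-fold lower and Aurka 3.06-fold lower. Ribosome biogenesis and MYC target genes had a median of -0.82, with 10 of 30 lower, among them Dkc1 at 2.71-fold and Srm at 3.54-fold. The 20 cholesterol synthesis genes had a median of -0.61, and 5 were lower, including Idi1 by 3.57-fold and Fdps by 2.87-fold. ATF4 and amino acid response genes stood apart at -0.32, with 5 of 34 lower and the cystine transporter gene Slc7a11 3.55-fold lower. The oxidative phosphorylation genes had a median of -0.15, and this list no longer stood apart when probe sets were averaged (-0.14).

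Melanocyte genes had a median of 0.78, with 6 of 20 higher and 1 lower. Mlana, a melanosome protein gene, was 17.5-fold higher and the transporter gene Slc45a2 6.32-fold higher, while Tyrp1 differed by -0.11. Schwann and glial markers had a median of 0.81, with 2 of 8 higher and 1 lower. S100b was 4.38-fold higher and Erbb3 2.70-fold higher, while Mbp was at least 2.14-fold lower. Sox10 belongs to both this list and the melanocyte list, so the 2 lists are not fully separate. Of 14 genes of MHC class I and antigen processing, 4 were higher and the median was 0.54. The peptide transporter gene Tap1 was 5.84-fold higher, and the immunoproteasome subunit gene Psmb9 at least 15.0-fold higher. Interferon response genes had a median of 0.39 with 4 of 30 higher, led by Ifi27l2a at 5.61-fold. Lysosome genes had a median of 0.44 and hypoxia and glycolysis genes one of 0.27, with 2 of 28 and 6 of 26 higher, among them Sgsh at 2.58-fold and Ndrg1 at 3.73-fold. Neural crest and stem cell genes stood apart at 0.35, with 2 of 19 higher and 1 lower. Aldh1a1 was at least 2.87-fold higher and Sox9 2.28-fold higher, while Nes was 2.05-fold lower. Secreted factors of senescent cells stood apart at 0.29, with 4 of 27 higher and 1 lower, and the matrix protease gene Mmp3 was 5.97-fold higher. Both calls ended when probe sets were averaged, at 0.21 and 0.18. The first also ended at the 75th percentile background (0.20), and the second when dim values were raised to the background (0.22).

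Other genes far higher at day 28 were Serpina3n at 36.5-fold, Rnase1 at 22.3-fold, Cdh5 at 18.7-fold, Prelp at 15.8-fold, H2-M3 at 13.8-fold, Dhrs3 at 12.9-fold, Sparcl1 at 10.3-fold, Id4 at 9.14-fold and Postn at 9.11-fold. Lcn2, which binds bacterial iron carriers, was at least 52.9-fold higher, Col20a1 at least 27.4-fold and Pcdh9 at least 23.2-fold, although the 2 probe sets of Pcdh9 above the background differed by 0.12 and 4.46 for day 28 against day 14. The lowest were Gask1b at 14.5-fold, Siglecg at 12.5-fold, Speer3 at 7.64-fold, the smooth muscle actin gene Actg2 at 5.91-fold, Sorbs2 at 5.66-fold, Rras2 at 5.20-fold and Ptprz1 at 4.92-fold. Pawr and the actin-binding protein gene Tagln were each 4.51-fold lower, Fbn2 was 4.43-fold lower, Bdh1 4.27-fold and Ankrd1 4.14-fold. At day 28 Siglecg (22.98), Speer3 (23.01) and Fbn2 (22.87) lay just above the background of 22.83, so their folds rest on values near it. H2-M3 (22.91) lay near the background of 22.62 at day 6. Below the background at day 28 were Ptchd4 at least 5.15-fold lower, Slc24a3 and Ska3 at least 3.52-fold lower and Prkcq at least 3.25-fold lower. Of the 389 genes that were 2-fold apart and had other probe sets above the background, 367 had them in the same direction and 207 had them 2-fold apart too.

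The lists for Ras-ERK output and for cell cycle inhibitors and p53 targets did not stand apart between days 6 and 28 as measured. The DNA replication and mitosis lists did, as given above. The Ras-ERK output genes had a median of 0.21, inside the random range of -0.19 to 0.23, and stood apart with the same median when probe sets were averaged, with Spry1, a feedback inhibitor, 4.95-fold higher. Cell cycle inhibitors and p53 targets had a median of 0.15, with 1 of 19 higher and 1 lower. Nras itself differed by -0.22, from 26.92 to 26.70, on its main probe set. Its 3 probe sets gave -0.83 to -0.22, and -1.12 to -0.44 for day 14 against day 6, and whether they detect the introduced gene is unknown. The inhibitor genes Cdkn2a and Cdkn1a differed by 0.54 and 0.15. Cth, an enzyme gene of cysteine synthesis, lay below the background on all arrays. The lists for NRF2 and antioxidant genes (-0.07), sulfur amino acid metabolism (-0.21), the unfolded protein response (0.17), mesenchymal and matrix genes (-0.08), fibroblast markers (0.06), macrophage and leukocyte markers (-0.19) and reference genes (-0.10) also lay inside their ranges. Of these, the mesenchymal and matrix list stood apart when probe sets were averaged (-0.27). Keratinocyte and endothelial markers had 4 and 2 members above the background.

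**Figure D1:**
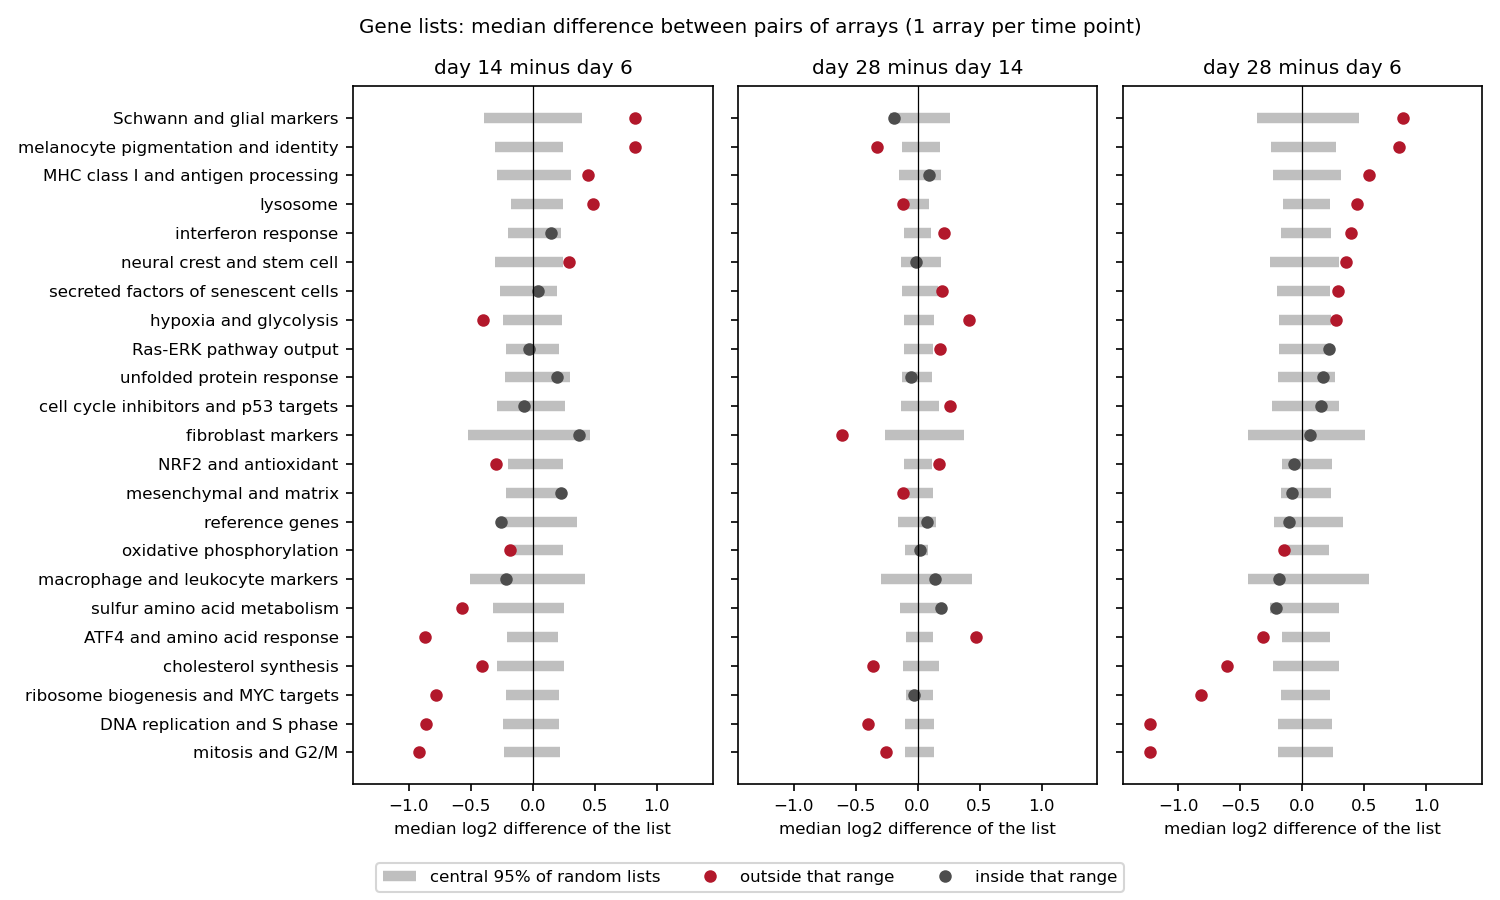
Median log2 difference of each ranked gene list (points, horizontal axis) for the 3 pairs of arrays, with the central 95% of 10000 random lists matched on level as grey bars and red for lists outside it. DNA replication and mitosis lie at -1.23 in the panel for days 28 and 6, and the ATF4 list lies at -0.87 for days 14 and 6 and at 0.47 for days 28 and 14.

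Day 14 against day 6 covers the first step. Some pigment genes were far higher at day 14, and the medians of the amino acid response, ribosome biogenesis and cell cycle lists were lower. Dct was 40.6-fold higher, Mlana 28.4-fold, Slc45a2 13.2-fold and Tyrp1 4.28-fold. The cystine transporter gene Slc7a11 was 5.76-fold lower, Chac1, which degrades glutathione, 3.58-fold lower and the serine synthesis gene Psph 3.41-fold lower. In all, 644 genes were 2-fold higher and 473 lower among 11885. At 1.5-fold the balance turned, with 1581 higher and 1713 lower. With the shift to equal hybridization controls, which again moves every gene alike, the counts were 557 and 632. This comparison shares the day 6 array with the one before, so an error of that array enters both.

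Melanocyte genes had a median of 0.82, with 10 of 21 higher and 1 lower, and Cdh1 was at least 3.33-fold higher. Schwann and glial markers had a median of 0.83, with S100b 7.09-fold higher. Lysosome genes stood at 0.49, MHC class I genes at 0.44 and neural crest and stem cell genes at 0.29, with 3 of 28, 3 of 14 and 3 of 19 higher. Sgsh was 5.39-fold higher, Gaa 2.58-fold and Tap1 3.11-fold. The neural crest call ended when probe sets were averaged (0.12). Other large differences were Col27a1 with a log2 difference of 4.25, Prelp at 17.3-fold, Dhrs3 at 15.3-fold, Scn1a at 14.9-fold, and Cnmd at least 11.5-fold, Lcn2 at least 10.4-fold, Adgb at least 7.38-fold and Lgi4 at least 6.70-fold higher. Col27a1 lay just above the background at day 6 (22.68 against 22.62).

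ATF4 and amino acid response genes had a median of -0.87, with 15 of 34 lower and 0 higher, and Mthfd2, a mitochondrial folate enzyme gene, was 2.86-fold lower. Mitosis genes had a median of -0.92 and DNA replication genes one of -0.86, with 10 of 29 lower in each. Ribosome biogenesis genes stood at -0.78, with 8 of 30 lower. Sulfur amino acid metabolism stood at -0.57, with 1 of 18 higher and 3 lower, and NRF2 and antioxidant genes at -0.30, with 2 of 29 higher and 4 lower. Gclm, a member of both lists, was 2.83-fold lower and Hmox1, which degrades heme, 3.94-fold lower, while Sod3 was at least 3.23-fold higher. Cholesterol synthesis stood at -0.41, hypoxia and glycolysis at -0.40 and oxidative phosphorylation at -0.18, the last of which ended when probe sets were averaged (-0.17). Siglecg was 13.7-fold lower, Speer3 8.50-fold, Msln 7.50-fold and Adh7 5.47-fold. At day 14 Siglecg (22.85) and Speer3 (22.86) lay near the background of 22.63. Ptchd4 was at least 5.92-fold lower, Lce1h at least 5.77-fold, the probe set annotated to Mir1949 at least 2.96-fold and Il34 at least 2.65-fold. Whether that probe set detects the microRNA itself is unknown. Lox was 4.99-fold lower on its main probe set, while another gave 0.11, and the main one lay just above the background at day 14 (22.66 against 22.63).

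Of the lists inside their ranges, the cell cycle inhibitors and p53 targets had a median of -0.07 with 5 of 19 lower, among them Sesn2 at 2.79-fold, Aen at 2.73-fold (another probe set gave -0.69), Gadd45a at 2.14-fold and Cdkn2a at 2.09-fold. Secreted factors (0.04) had 5 of 28 higher and 5 lower, and Ras-ERK output (-0.03) had 3 of 30 higher and 3 lower, with Fosl1 3.67-fold lower and Fos 2.52-fold higher. The unfolded protein response (0.20), interferon response (0.15), macrophage and leukocyte markers (-0.22) and fibroblast markers (0.37) also lay inside. The fibroblast list, with Ogn 9.06-fold and Col3a1 2.08-fold higher, stood apart when probe sets were averaged (0.95) and at the 75th percentile background (0.48). The macrophage marker Lyz2 was 6.09-fold higher and Cd68 2.17-fold lower. Mesenchymal and matrix genes (0.23) lay inside the range as measured and outside it in 4 alternatives. Reference genes had a median of -0.25, near the lower end of their range at -0.28, and stood apart when probe sets were averaged (-0.40).

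Day 28 against day 14 covers the second step, with the fewest genes apart. The medians of the amino acid response, hypoxia and interferon lists were higher at day 28, and those of the cell cycle, cholesterol and pigment lists were lower. The inhibitor gene Cdkn2a was 3.05-fold higher, Chac1 2.33-fold and Hmox1 2.47-fold. Tyrp1 was 4.62-fold lower and Dct 2.20-fold lower. In all, 255 genes were 2-fold higher and 170 lower among 11692.

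ATF4 and amino acid response genes had a median of 0.47, with 2 of 34 higher. Hypoxia and glycolysis genes stood at 0.41, with 6 of 26 higher, including Egln3 at 3.35-fold, Mxi1 at 2.18-fold and Car9, a carbonic anhydrase gene, at least 2.29-fold. Egln3 (22.81) lay near the background of 22.63 at day 14. Interferon response genes stood at 0.22, with Ifi27l2a 4.84-fold higher. Cell cycle inhibitors and p53 targets stood apart at 0.26 with 1 of 19 higher, secreted factors at 0.19 with 4 of 27 higher and 2 lower, and Ras-ERK output at 0.18 with 4 of 30 higher and 2 lower. In these lists Mmp13 was 3.35-fold higher, Igfbp5 5.08-fold lower on its main probe set and by -0.32 on another, Fosl1 2.34-fold higher and Dusp1 2.63-fold lower. NRF2 and antioxidant genes stood at 0.17, a call that ended when probe sets were averaged (0.13).

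Melanocyte genes had a median of -0.33, with 8 of 21 lower and 0 higher. DNA replication stood at -0.40, cholesterol synthesis at -0.36 and mitosis at -0.26, with 0 members 2-fold apart in any of the 3 lists. Fibroblast markers stood at -0.61, with Ogn 3.69-fold and Col3a1 2.20-fold lower and Pdgfra 2.36-fold higher, and this call ended at the 75th percentile background (-0.17). Mesenchymal and matrix genes and lysosome genes stood at -0.12 each. Sulfur amino acid metabolism (0.19), the unfolded protein response (-0.06), neural crest genes (-0.01), MHC class I (0.09), oxidative phosphorylation (0.02), ribosome biogenesis (-0.03), leukocyte markers (0.14), glial markers (-0.19) and reference genes (0.07) lay inside their ranges. Of these, the sulfur list stood apart when probe sets were averaged (0.24) and at the 75th percentile background (0.22), MHC class I when they were averaged (0.19) and without shared probe sets (0.23), and glial markers, at the same median, when dim values were raised to the background.

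Pcdh9 was 22.0-fold higher at day 28 than at day 14 on its main probe set, while another gave 0.12. The main one lay just above the background at day 14 (22.70 against 22.63). Rnase1 was 17.1-fold higher, Igf2 13.6-fold, Prkcb 12.7-fold, Nefl 10.2-fold and Col20a1 6.89-fold. Nefl (22.89) also lay near the background at day 14. Kcnh1 was at least 7.37-fold higher, Ryr3 at least 6.12-fold, Tspoap1 at least 5.25-fold and Prss22 at least 4.72-fold. Gask1b was 5.95-fold lower, Adgb 5.20-fold, Ptprz1 4.99-fold and Stox2 4.94-fold. Adgb (23.13) lay near the background of 22.83 at day 28. Below the background at day 28 were Filip1 at least 3.37-fold lower, Dusp8 at least 3.23-fold, Cdh1 at least 2.89-fold and Lmcd1 at least 2.87-fold, and the other probe sets of Dusp8 gave -1.05 and 0.03.

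**Figure D2:**
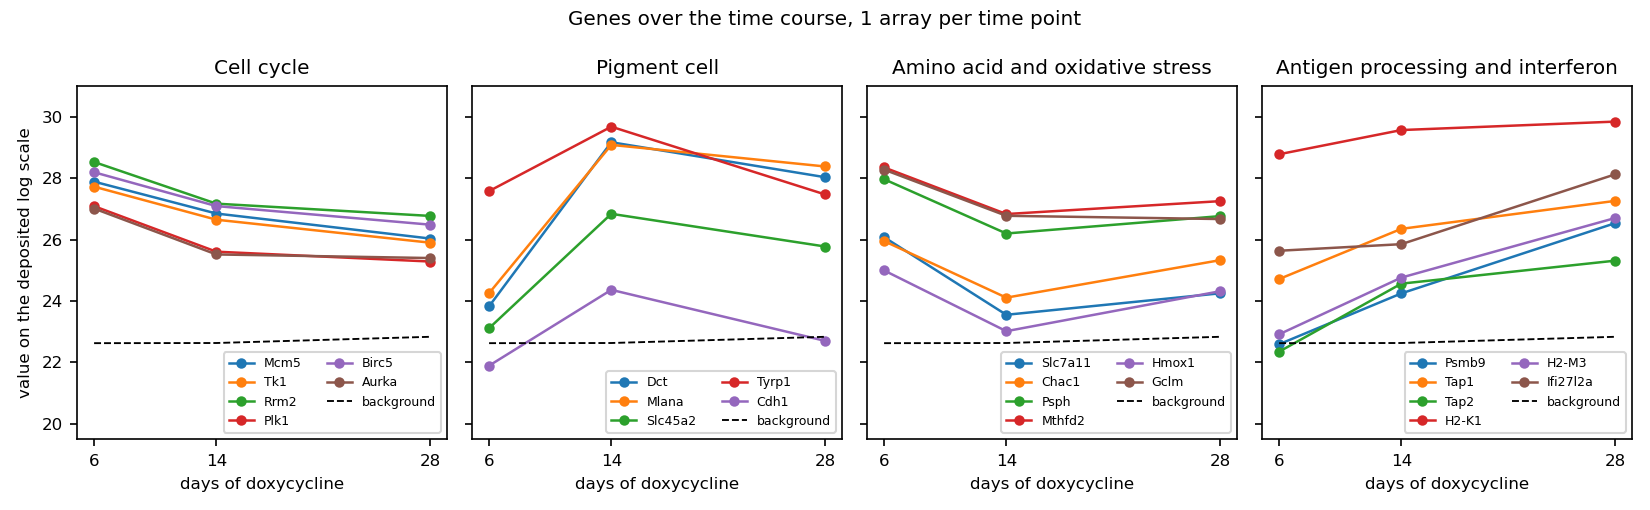
Values of single genes on the deposited log scale (vertical axis) against days of doxycycline (horizontal axis), 1 array per time point, with the background as a dashed line. Dct goes from 23.83 at day 6 to 29.17 at day 14 and 28.03 at day 28, and Slc7a11 from 26.08 to 23.55 and 24.25.

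Over the whole course, 1395 of 12015 genes (11.6%) were 2-fold apart in at least 1 step. Of these, 544 were higher at day 14 than at day 6 with no 2-fold second step, and 413 were lower in that way. Another 166 were higher and 95 lower in the second step alone. Both steps went up for 43 genes, such as Csn3, Cdh5, Lcn2 and Igf2, and down for 9. Higher then lower described 73 genes, such as Tyrp1, Dct and Slc45a2, and lower then higher 52 genes, such as Chac1, Hmox1, Cdkn2a and Cd68. Both steps share the day 14 array with opposite signs, so an error of that array alone gives reversals. Every list with opposite medians in the 2 steps carries the same limit, such as the ATF4, melanocyte, hypoxia and glycolysis, NRF2 and lysosome lists. The size of such an error cannot be had from 1 array per time point.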

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

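The shift of each array to equal hybridization controls was chosen after the data were examined, and the other alternatives were fixed before. Centring and quantile normalization moved nothing, because the deposited columns already held the same values, so they show nothing about stability. The shift moves all genes alike, so it changed counts of genes and left the calls of lists as they were. It would also move each list median and log2 difference by a common amount. That amount was -0.12 for day 28 against day 6, -0.08 for day 14 against day 6 and -0.04 for day 28 against day 14. It gave 624 higher and 652 lower for day 28 against day 6, 557 and 632 for day 14 against day 6, and 236 and 178 for day 28 against day 14. Counts of genes depended on the size of difference. At 1.5-fold they were 1832 higher and 1454 lower for day 28 against day 6, 1581 and 1713 for day 14 against day 6, and 880 and 516 for day 28 against day 14. At 3-fold they were 303 and 91, 251 and 65, and 87 and 47. Genes with 2 or more probe sets, all 2-fold apart, numbered 161 and 135, 146 and 95, and 41 and 42, fewer by construction. With values below the background raised to it, the counts were 661 and 403, 558 and 389, and 201 and 123, in the same order. The median of the melanocyte list for day 28 against day 6 was then 0.67. Genes not flat over the course numbered 4030 at 1.5-fold. Without the settings that could move nothing, the other 36 of 54 counts stayed within 1.5 times the reported ones, and so did the number of lists standing apart in 15 of 15 cases. Of 345 values for single lists, 322 kept their call, 14 gained one and 9 lost one. Of 1341 values for named genes, 1190 moved by less than the disagreement between probe sets and 150 by more. Igfbp5 for day 14 against day 6 turned from 1.63 to -0.0019 without the probe sets marked as shared between transcripts, and the probe set itself was the cause. Values near the background limit all of this, since the lowest ones differ by many log2 units between arrays.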

Other observations

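Chosen after the result was seen were the tests of a noisier array, RNA degradation at day 6, RNA quality on the later arrays and a smaller melanocytic share, and the separate tests of chromosomes 2, 17 and 19 and of 4 parts of chromosome 2. The joint test of the 3 chromosomes and the test of gene length were set before their results were seen, though the medians of whole chromosomes were known by then. The families below were picked by name from 18 looked at after the values were seen.

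Collagen genes as a family had a median log2 difference of 0.80 for day 14 against day 6, with 9 of 27 2-fold higher and 0 lower, against a random range of -0.31 to 0.19. For day 28 against day 14 the median was -0.22, with 3 of 26 higher and 5 lower, and for day 28 against day 6 it was 0.67, with 7 of 24 higher and 1 lower. Among its members, Col11a1 stood at 22.73, 24.96 and 23.68 and Col9a1 at 23.74, 25.77 and 25.51 in order of time. The H2 genes had a median of 0.74 for day 28 against day 6, with 6 of 13 higher. All 4 Slfn genes described were higher in that comparison, and Slfn8 went through 22.76, 24.58 and 25.63. The cornified envelope genes Lce had a median of -0.71, with 4 of 8 lower. These genes were named after their values were seen, as were those that follow.

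Pigment genes did not move as a block. Mitf, the master regulator of the lineage, stood at 23.67, 26.10 and 25.80, and Mlph at 24.56, 26.50 and 25.78. Pax3 stood at 27.49, 27.55 and 27.58 and Sox10 at 27.62, 28.34 and 28.50, while Tyr and Kit lay below the background on all arrays. Notch3 stood at 23.87, 25.17 and 26.53. Among 10092 probe sets without a single gene name, 221 were 2-fold higher and 122 lower for day 28 against day 6, 249 and 118 for day 14 against day 6, and 63 and 92 for day 28 against day 14.

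Expressed genes set the day 6 array apart, with a robust SD of differences against day 6 that was 1.71 times that between days 14 and 28. Noise of the day 6 array that is alike at all levels would widen dim genes too. For 6179 genes below the background the ratio was 1.05 (bootstrap range 1.01 to 1.08), which argues against that kind of noise only. Dim genes already had robust SDs of 0.53 to 0.57, which could hide noise that grows with signal. Probe sets of one gene disagreed more against day 6, with robust SDs of 0.24 and 0.22, than between days 14 and 28, with 0.17. A day 6 array noisier in expressed genes therefore stays open. RNA degradation at day 6 would raise its 3' over 5' difference, and the largest excess over both other arrays was -0.15, which argues against it in that direction only. Both later arrays had more 3' bias than day 6, by at least 0.14 for Actb and Gapdh, so lower RNA quality on those arrays stays open. A difference of the cells at day 6, of time or of the single culture, may remain, and these cannot be separated with 1 array per time point.

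Dct, Mlana and Slc45a2 were far lower at day 6 than at day 14, and a smaller share of melanocytic cells at day 6 could lower them, along with every gene confined to those cells by about the same factor. The median of the 18 melanocyte genes above the background on both arrays was 0.79, with an upper bootstrap limit of 1.96, and Dct was the highest at 5.34. The genes of this list thus did not share 1 factor. That cannot decide about the share of cells. The highest member must lie above the median, and some members of the list are also expressed by other cells. With all 21 members described, the 2 below the background at day 6 alone placed above every other and the 1 below it at day 14 alone below every other, the median was 0.82 with an upper limit of 2.10. A first test, the interquartile range of these genes over that between probe sets, gave 5.01 with a range of 1.53 to 12.2 and settled nothing, so the median was tested in its place. A smaller share of melanocytic cells and regulation within the cells, as hypotheses, both remain open.

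Genes of chromosomes 2, 17 and 19, picked from 20 chromosomes in 3 comparisons, lay above the median of all genes by 0.08, 0.07 and 0.12 for day 28 against day 14, and a copy number difference in part of the cells might do this. The joint test, in which each chromosome's genes were divided in order into 2 equal parts, failed with a lowest part at -0.0166, and the chromosomes were separated only after that. For chromosome 2 the parts lay at -0.0166 and 0.20, which argues against the whole chromosome, while on chromosome 17 the lower part lay at 0.0621 but day 28 against day 6 gave 0.04, and on chromosome 19 the lower part lay at 0.0822, which left copy number open for both. Gene length does not account for the shift, since 87.6% of the mean excess was kept once trends on length and level were removed. In 4 equal parts, chromosome 2 lay at 0.0004, -0.02, 0.27 and 0.12, and at -0.03, -0.04, 0.23 and 0.18 for day 28 against day 6, which shares the day 28 array, so a difference of its later part stays open beside regulation of neighbouring genes and GC content, and these were not told apart.

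Other chromosomes also lay outside their random ranges, and those beyond 0.1 were as follows. Chromosome 18 lay at 0.17 and chromosome 16 at 0.11 for day 14 against day 6, chromosome 18 lay at 0.12 for day 28 against day 6, and chromosome 16 lay at -0.11 for day 28 against day 14.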
